A study of Homo sapiens with 8 samples.

How the data were processed

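Total RNA of Reh cells was labelled with biotin and hybridized to 8 Affymetrix U133 Plus 2.0 arrays, 2 for each of 4 transfections. The labels name the arrays of each group as biological replicates 1 and 2. The deposited values are log2 probe set intensities made by the authors with RMA, which corrects background, sets the arrays to a common distribution and summarises the probes of a set, per the submitters' processing notes. The RMA version, the chip definition used and any filter are not given in the sources used here. The log base was read from the values, which reached 14.6, above the natural log of a 16-bit scanner maximum (11.1). Sorted values of the 8 arrays differed from their mean by at most 0.0853, and no value was missing. Quantile normalization of this kind removes any shift that affects most transcripts in 1 direction, and log2 values near background understate the folds of dim genes.

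The table held 54675 probe sets. The 62 control probe sets were left out, and so were 30132 probe sets that did not reach log2 5 on at least 2 arrays, which left 24481. The file holds no detection calls, so a mean under log2 5 is treated as close to background and a fold from such a mean as uncertain. GEO's platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. Of the first, 41043 matched the reference gene table by gene identifier and 0 symbols needed an update. Among the tested probe sets, 20746 had 1 symbol and represented 11449 genes. No genome build is named in the sources used here, so no coordinates are given.

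Each probe set was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean per group and 1 spread shared by the 4 groups (4 residual degrees of freedom, 3.54 prior degrees of freedom). There were 6 comparisons: CBFA2T3 shRNA, IKKβ(EE) and both against control shRNA, both against either alone, and the interaction, which is the effect of both minus the sum of the single effects. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison, and probe sets under an adjusted p of 0.05 were called. The number of arrays limits the precision: the median standard error of a difference was 0.15 on the log2 scale, and an exact permutation test of 2 arrays against 2 cannot give a p under 0.333. Errors after ± are standard errors (SE) of the fit, except where SD is written.

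Whether equal replicate numbers marked arrays that deviated together was checked on the values. The differences between replicates 2 and 1 correlated across probe sets in all 6 pairs of groups, from 0.34 to 0.58, so the numbers were taken to pair the arrays. The pairing comes from these correlations, since the labels do not say that a number marks a shared day or batch. A fit with the replicate number as a block is given beside a result where it changed the call or moved a count by over 1.5 times.

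Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene (the one with the highest mean). Of the 25 lists, 24 held at least 5 tested genes, and p-values were adjusted over the 24. Some lists share members, so lists that passed together are not independent results. Each list that passed is followed by the adjusted p from camera with an inter-gene correlation estimated from the residuals. With that estimate 0 of the 24 lists passed in any of the 6 comparisons. The lists, groups, tests, the rule for naming genes and the alternatives, apart from the 3 that combine the replicate block with an estimated correlation, with fry or with a left-out array, were fixed before the data were examined. The rule named, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among called single-symbol probe sets whose arrays did not overlap between groups. Only 1 probe set per gene, the one with the highest mean, entered this ranking. For both transfections against either alone the limit was 5 and 5. It also named CBFA2T3, IKBKB and CSF1R, and from each list up to 2 called members at either end, or, without a called member, the members with the largest and smallest change as values.

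The fits were tested on simulated data drawn with the arrays' own means and spread, with 200 changed probe sets among 24481 in each of 10 draws. For CBFA2T3 shRNA against control, 81.1% of 2-fold and 98.9% of 4-fold changes were recovered, with 5.62% false calls. For the interaction 30.0% of 2-fold and 95.5% of 4-fold changes were recovered, with 5.74% false calls. Camera found 20 of 20 simulated lists of 30 genes shifted by 0.3 and called 0 of 20 unshifted lists. All simulated genes varied independently and without a replicate difference. The false calls of lists whose members vary together were therefore not tested.

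Alternatives were no floor and a floor at log2 6, trend and robust moderation, array weights, cyclic loess, equal array medians, 1 probe set per gene, the replicate block, the arrays of the 2 compared groups alone, an estimated inter-gene correlation, fry in place of camera, the mean of all probe sets of a gene, and leaving out each array in turn. When 1 array is left out, its partner is assumed to vary like the other groups, and its group no longer adds to the shared spread. Leaving out either array of a group outside a comparison therefore gives the same result, through the spread alone. Without the replicate block, leaving out an array of a compared group also shifts that group by what the replicates differed. Because the shRNA and IKKβ(EE) comparisons share the 2 control arrays, their overlap was set beside 100 simulations of unchanged groups against the same controls.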

Results

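Gene expression was measured in Reh, an established human B-cell precursor line that the study's design text traces to acute lymphoblastic leukemia and the sample labels file under non-Hodgkin lymphoma. Cells had received a control shRNA (the sample titles call these arrays mock), an shRNA against CBFA2T3, a constitutively active IκB kinase β called IKKβ(EE), or the CBFA2T3 shRNA together with IKKβ(EE). CBFA2T3 encodes a transcriptional corepressor of the ETO family, and IKKβ, the product of IKBKB, is the kinase that releases NF-κB from its inhibitors. Each of the 4 groups had 2 arrays, and the labels do not say whether the cells with IKKβ(EE) alone also carried a control shRNA. Arrays correlated with each other at 0.978 to 0.995. The first principal component held 52.4% of the variance, with the control arrays at -44.6 and -34.2 and the arrays with both transfections at 20.3 and 63.7. The second held 24.3% and placed the CBFA2T3 shRNA arrays (-24.8 and -37.2) opposite the IKKβ(EE) arrays (22.7 and 33.1). The third held 11.2%, and replicate 2 lay above replicate 1 in all 4 groups.

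The first question was whether the targeted genes had changed as the labels say. CBFA2T3 expression on its single probe set was 9.26 ± 0.05 (log2, SD, n = 2) with the control shRNA, 8.26 ± 0.21 with the CBFA2T3 shRNA, 8.90 ± 0.01 with IKKβ(EE) and 8.03 ± 0.28 with both. The level with the CBFA2T3 shRNA was 50.0% of control, a log2 change of -0.999 ± 0.16 (95% confidence interval -1.38 to -0.62). It narrowly missed the threshold (limma adjusted p = 0.0518) and passed it with the replicate block (adjusted p = 0.01002). With both transfections CBFA2T3 fell by 1.23 ± 0.16 against control (42.8% of control, adjusted p = 0.00938), and against IKKβ(EE) alone the change was -0.87 ± 0.16 (adjusted p = 0.104, or 0.0255 with the replicate block). IKKβ(EE) alone left CBFA2T3 at 78.1% of control (log2 change -0.36 ± 0.16, adjusted p = 0.540). On 1 of its 3 probe sets IKBKB rose by 6.63 ± 0.30 with IKKβ(EE) (adjusted p = 0.000312) and by 7.71 ± 0.30 with both (adjusted p = 0.000148). The control mean there, 4.0, lay near background. The other two IKBKB probe sets did not pass the test, with changes under IKKβ(EE) of 0.32 ± 0.17 and 0.26 ± 0.19. On the probe set that rose, the IKBKB level was 2.13-fold higher with both than with IKKβ(EE) alone (log2 1.09 ± 0.30, adjusted p = 0.171). CSF1R, the receptor of macrophage colony-stimulating factor, which published work on CBFA2T3 and NF-κB in Hodgkin lymphoma concerns, had means from 4.86 ± 0.35 to 5.21 ± 0.09 (SD, n = 2) in the 4 groups, close to background. Its change with both transfections against control was 0.12 (95% confidence interval -0.28 to 0.53, adjusted p = 0.701), and it passed the test in none of the 6 comparisons, with the smallest adjusted p at 0.564. Without 1 array the change of CBFA2T3 with its shRNA alone ranged from -1.14 to -0.85 (adjusted p from 0.0381, without either array of both transfections, to 0.436). With both transfections against control it failed the test without control 1 (adjusted p = 0.0665) and control 2 (0.0903), and against IKKβ(EE) alone it passed without replicate 1 of both (0.0400).

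**Figure D1:**
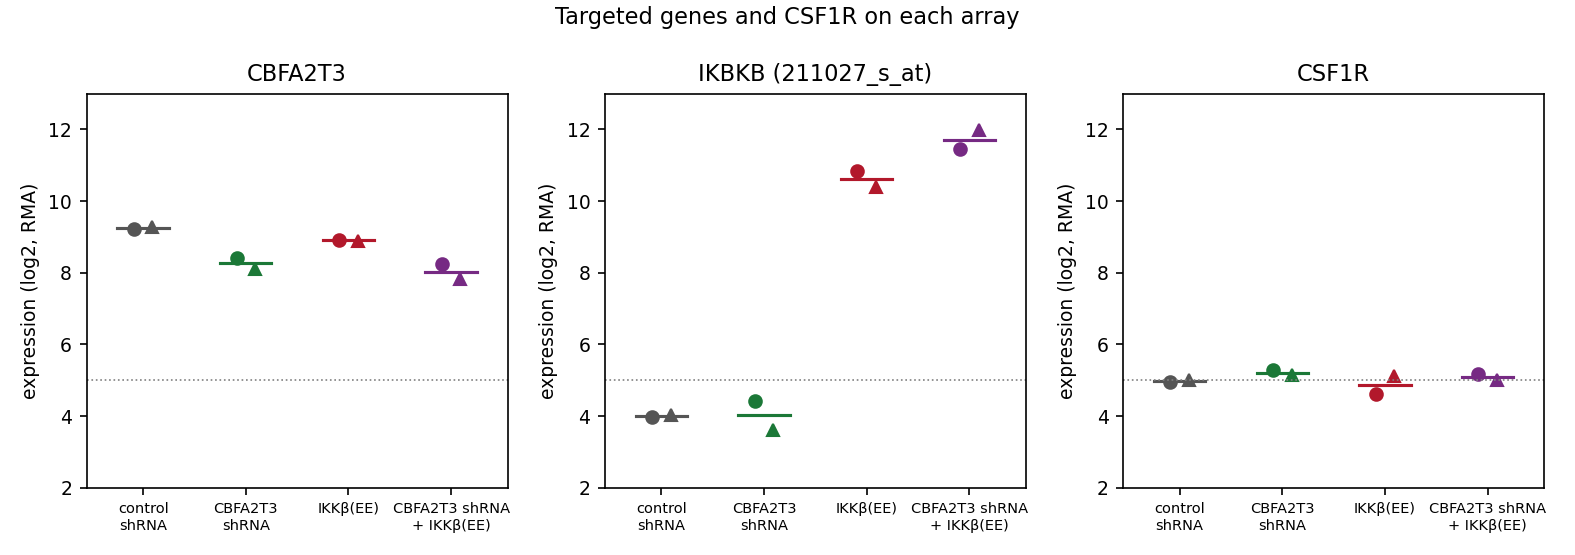
Expression (log2, RMA) of CBFA2T3, IKBKB (the probe set that rose) and CSF1R on each array, by group; circles are replicate 1, triangles replicate 2, bars the mean of the 2 arrays, and the dotted line is the floor at log2 5. CBFA2T3 means were 9.26, 8.26, 8.90 and 8.03, IKBKB was near 4.0 without IKKβ(EE) and at 10.62 and 11.71 with it, and CSF1R stayed between 4.86 and 5.21.

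The next comparison asked what the CBFA2T3 shRNA changed on its own. TOX, a nuclear factor of developing lymphocytes, rose by 3.50 ± 0.35 on the log2 scale (adjusted p = 0.0252), and LCK, a Src-family kinase of T-cell receptor signalling, rose by 2.05 ± 0.23 (adjusted p = 0.0280). RSAD2, an interferon-induced antiviral enzyme, rose 6.40-fold from 6.90 to 9.58 (adjusted p = 0.0334). ANXA1 (2.64 ± 0.41), CDC42EP3 (3.22 ± 0.42), SUCNR1 (2.39 ± 0.31), AK5 (2.35 ± 0.35), AGR2 (2.30 ± 0.35), ROBO1 (2.06 ± 0.33) and the divergent transcript TOX-DT (1.94 ± 0.23) also rose. Of these, only RSAD2, AGR2 and ROBO1 had a control mean above log2 5, so the other folds are uncertain. The largest falls were those of TBC1D9 (-2.12 ± 0.20), the heparan sulfate proteoglycan SDC2 (-1.99 ± 0.26), COX7A2L (-1.93 ± 0.20), RASSF5 (-1.88 ± 0.26), the transcriptional coregulator MN1 (-1.77 ± 0.18), the chemokine receptor ACKR3 (-1.75 ± 0.26) and PREX1 (-1.75 ± 0.15). PROM1, which encodes the progenitor surface marker CD133, fell by 1.72 ± 0.26, CEACAM1 by 1.72 ± 0.16 and B4GALT6 by 1.51 ± 0.19.

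Among gene groups, interferon response genes rose with the CBFA2T3 shRNA: 42 of 51 were higher, with a median log2 change of 0.40 and an adjusted p of 2.34e-08 (adjusted p = 0.835 with an estimated correlation). RSAD2, ISG15 (1.20 ± 0.19, adjusted p = 0.0482) and OAS2 (0.73, adjusted p = 0.0441) were called, 15 members were called with the replicate block, and 19 rose when adjusted over the list alone. OAS2 lay outside the naming rule and was chosen after its values were seen. Cholesterol synthesis genes rose as a group (21 of 24 higher, median 0.33, adjusted p = 9.59e-05, and adjusted p = 0.835 with an estimated correlation), although 0 members passed singly and 4 did with the replicate block. STARD4, a sterol transporter, had the largest change there (0.97 ± 0.42, adjusted p = 0.312, or 0.0404 with the replicate block). Genes associated with Hodgkin lymphoma also rose as a group (29 of 36 higher, median 0.23, adjusted p = 0.0294, and adjusted p = 0.995 with an estimated correlation), with 0 members called and LGALS1 at 2.53 ± 0.74 (adjusted p = 0.162, or 0.00691 with the replicate block). DNA replication and S-phase genes fell as a group (8 of 48 higher, median -0.14, adjusted p = 0.0354, and adjusted p = 0.995 with an estimated correlation), with 0 members called. The NF-κB targets did not pass (0 of 54 called, adjusted p = 0.358). In the B-cell list SPIB (1.74 ± 0.27) and TCL1A (0.99 ± 0.16) rose, and the list did not pass (adjusted p = 0.994), with a mean change of 0.09 although the test's direction was down. Of the 29 corepressor partners of CBFA2T3 0 were called, and LMO2 stood at -1.77 ± 0.32 (adjusted p = 0.0631, or 0.00836 with the replicate block). The immediate early gene FOS stood at 3.19 ± 0.53 (adjusted p = 0.0539, or 0.00345 with the block), and with the block its list passed too (adjusted p = 0.0113), as did apoptosis regulators (0.0198) and stress response genes (0.0258). With the block these 3 had an adjusted p = 0.881, 0.881 and 0.924 with an estimated correlation. Members called with the block were 5 of the Hodgkin list (0 without it), 1 S-phase gene (0), 5 NF-κB targets higher and 2 lower (0), 6 B-cell genes higher and 1 lower (2 and 0), and 2 corepressor partners higher and 1 lower (0).

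In all, 169 probe sets changed with the CBFA2T3 shRNA, 72 higher and 97 lower. An unadjusted p under 0.05 was found for 3977. With the replicate block 1890 were called, including all 169. The count depended on single arrays: it was 0 without control 1, control 2 or shRNA replicate 2, 55 without shRNA replicate 1, 20 without either IKKβ(EE) array, and 297 without either array of both transfections. The Hodgkin and S-phase calls were lost without control 1 (adjusted p = 0.0654 and 0.126) and without shRNA replicate 2 (0.285 and 0.495).

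A further comparison asked what IKKβ(EE) changed on its own. The largest rise was that of HLA-DQA1, an MHC class II chain, from 4.20 ± 0.34 (SD, n = 2) to 11.39 (log2 change 7.19 ± 0.51, adjusted p = 0.00416). LAMP3, a marker of mature dendritic cells, rose by 6.08 ± 0.55, the survival factor BCL2A1 by 5.43 ± 0.42 (adjusted p = 0.00458), and the chemokines CXCL10 and CXCL11 by 5.41 ± 0.54 and 5.39 ± 0.26. EBI3, a cytokine subunit, rose by 5.10 ± 0.54, the B-cell surface gene MS4A1 (CD20) by 4.91 ± 0.46, ANXA1 by 3.63 ± 0.41, and the death receptor gene FAS by 3.54 ± 0.40. SRGN rose by 4.19 ± 0.42 from a level of 7.14, the only one of these 10 with a control mean well above the floor (FAS stood at 5.02). MN1 (-1.37 ± 0.18, adjusted p = 0.0399) and RASSF10 (-0.96 ± 0.12, adjusted p = 0.0376) were the only genes called lower.

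The NF-κB target list rose with IKKβ(EE): 53 of 54 genes were higher, the median change was 1.26, 11 were called over all probe sets and 41 when adjusted over the list alone (adjusted p = 1.15e-41, and adjusted p = 0.202 with an estimated correlation). With the replicate block 34 were called. Cytokines, chemokines and their receptors (7 of 44 called, 22 adjusted over the list alone, median 0.79) rose with an adjusted p of 1.02e-21 (adjusted p = 0.202 with an estimated correlation). Antigen presentation genes rose as well, with 30 of 32 higher, HLA-DQA1 and TAP1 (1.31 ± 0.16) called, 23 called when adjusted over the list alone, and an adjusted p of 2.12e-23 (adjusted p = 0.0501 with an estimated correlation). Genes associated with Hodgkin lymphoma (4 of 36 called, 17 adjusted over the list alone, EBI3 and SOCS1 at 3.27 ± 0.41 among them) and interferon response genes (1 of 51 called, CXCL10, and 22 adjusted over the list alone) rose with adjusted p of 7.62e-19 and 1.36e-16, both with an adjusted p = 0.211 with an estimated correlation. Immediate early genes (0 of 33 called, EGR1 at 3.72 ± 0.52 with adjusted p = 0.0520, or 0.00691 with the block), p53 targets (1 of 30, FAS), apoptosis regulators (2 of 33, BCL2A1 and FAS) and B-cell genes (1 of 40, MS4A1) passed with adjusted p of 1.60e-08, 5.13e-05, 0.00454 and 0.0213, and each had an adjusted p = 0.505 with an estimated correlation. NF-κB pathway components passed with 0 of 32 called (adjusted p = 0.00413, and adjusted p = 0.202 with an estimated correlation). Several called genes stand in more than 1 list. BCL2A1 is in the NF-κB and apoptosis lists, FAS in the p53 and apoptosis lists, and EBI3 in the NF-κB and Hodgkin lists. CXCL10 is in the NF-κB, cytokine and interferon lists. G2/M genes (2 of 42 higher, median -0.21, adjusted p = 0.000121), S-phase genes (2 of 48 higher, median -0.24, adjusted p = 0.000121) and MYC and ribosome biogenesis genes (4 of 39 higher, median -0.23, adjusted p = 0.00203) fell as groups with 0 members called, and all had an adjusted p = 0.729 with an estimated correlation. With the replicate block the heat shock list passed as well, lower (adjusted p = 0.0356, and adjusted p = 0.519 with an estimated correlation). The block raised the called members to 19 of 44 cytokine, 15 of 32 antigen presentation, 19 of 36 Hodgkin, 14 of 51 interferon, 10 of 33 immediate early, 6 of 30 p53, 4 of 33 apoptosis and 3 of 32 NF-κB pathway genes, and to 4 B-cell genes higher and 1 lower.

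With IKKβ(EE) alone 56 probe sets were called, 54 higher and 2 lower, and 2390 had an unadjusted p under 0.05. With the replicate block 831 were called (724 higher, 107 lower), all 56 among them. Left-out arrays gave 5 (control 1), 6 (control 2), 13 (IKKβ(EE) replicate 1), 10 (IKKβ(EE) replicate 2) and 214 (either array of both transfections). Without control 1 the B-cell and MYC lists no longer passed (adjusted p = 0.160 and 0.954), without control 2 the G2/M list (0.109), and without IKKβ(EE) replicate 2 the B-cell and S-phase lists (0.199 and 0.151), while the MYC list then turned to the opposite direction (0.918).

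Both transfections together were compared with control next. HLA-DQA1 (7.38 ± 0.51), MS4A1 (7.33 ± 0.46), LAMP3 (7.17 ± 0.55) and BCL2A1 (7.13 ± 0.42) were more than 100-fold above control, with adjusted p from 0.000482 to 0.00147. The chemokine CCL4 rose by 6.46 ± 0.74, CXCL11 by 5.46 ± 0.26, CXCL10 by 5.12 ± 0.54, and CCR7, a homing receptor of lymphocytes and dendritic cells, by 5.08 ± 0.24 (adjusted p = 0.000185). EBI3 (5.76 ± 0.54) and the actin-bundling gene PLS3 (5.47 ± 0.49) completed the 10 largest rises under the naming rule, all from control means under log2 5. The IKBKB probe set that rose by 7.71 was left out by that rule. PROM1 fell by 2.66 ± 0.26 from 9.02 to 6.36 (adjusted p = 0.00396), and FGFBP2 (-2.10 ± 0.21), SORBS2 (-2.07 ± 0.24), MN1 (-2.06 ± 0.18), TBC1D9 (-2.05 ± 0.20), RASSF5 (-1.94 ± 0.26), TRNP1 (-1.86 ± 0.30), INSC (-1.83 ± 0.27), SHANK3 (-1.79 ± 0.19) and COX7A2L (-1.76 ± 0.20) followed.

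Of the 54 NF-κB targets 40 were called higher and 0 lower (49 when adjusted over the list alone, median 1.86, adjusted p = 1.32e-31, and adjusted p = 0.226 with an estimated correlation). Interferon response genes had 30 of 51 called higher (median 0.81), cytokines and their receptors 26 of 44 higher with only IL7R called lower (-0.76 ± 0.15), and antigen presentation genes 12 of 32 higher. Their adjusted p were 7.68e-21, 7.31e-16 and 5.03e-10, each with an adjusted p = 0.190 with an estimated correlation. GBP2, an interferon-induced GTPase, rose by 4.27 ± 0.36 and TAP1, a peptide transporter, by 2.03 ± 0.16. Of the genes associated with Hodgkin lymphoma 24 of 36 were called higher (adjusted p = 7.14e-18, and adjusted p = 0.226 with an estimated correlation), CCL5 among them (4.48 ± 0.32). Immediate early genes (11 of 33 called, EGR1 at 4.43 ± 0.52), p53 targets (5 of 30), apoptosis regulators (4 higher and 1 lower of 33) and NF-κB pathway components (4 of 32, NFKB2 at 2.41 ± 0.50 and RELB at 2.01 ± 0.48) passed upward, with adjusted p of 3.92e-09, 5.04e-05, 6.16e-05 and 0.00314. With an estimated correlation these had an adjusted p = 0.460, 0.472, 0.269 and 0.190. G2/M genes (0 of 42 higher, 3 called, TPX2 at -0.84 ± 0.18) and S-phase genes (3 of 48 higher, 1 called, PRIM1 at -0.97 ± 0.23) fell as groups, with adjusted p of 4.53e-09 and 2.28e-07 (adjusted p = 0.541 and 0.681 with an estimated correlation). Members called with the block were 11 G2/M and 21 S-phase genes lower, and 24 antigen presentation, 24 immediate early, 12 p53 and 9 NF-κB pathway genes higher, with 12 apoptosis regulators higher and 2 lower. Of 40 B-cell genes 7 were called higher, SPIB (2.09 ± 0.27) among them, and 2 lower, ERG (-0.99 ± 0.21) and BCL11A (-0.70 ± 0.16). T-cell and NK-cell genes had 3 of 12 called higher, GATA3 (2.45 ± 0.49) and LCK (1.80 ± 0.23) among them, and 1 lower, and myeloid genes 3 of 14 higher, including the neutrophil oxidase gene NCF1 (1.56 ± 0.24). Of the 29 corepressor partners RUNX2 (3.72 ± 0.45) and ID2 (1.66 ± 0.32) rose and LMO2 (-1.60 ± 0.32) fell. The block called 6 B-cell, 3 corepressor and 1 myeloid genes lower. The B-cell, T-cell, myeloid and corepressor lists did not pass (adjusted p = 0.762, 0.287, 0.287 and 0.606), and the B-cell list had a median of -0.18 and a mean of 0.23.

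**Figure D2:**
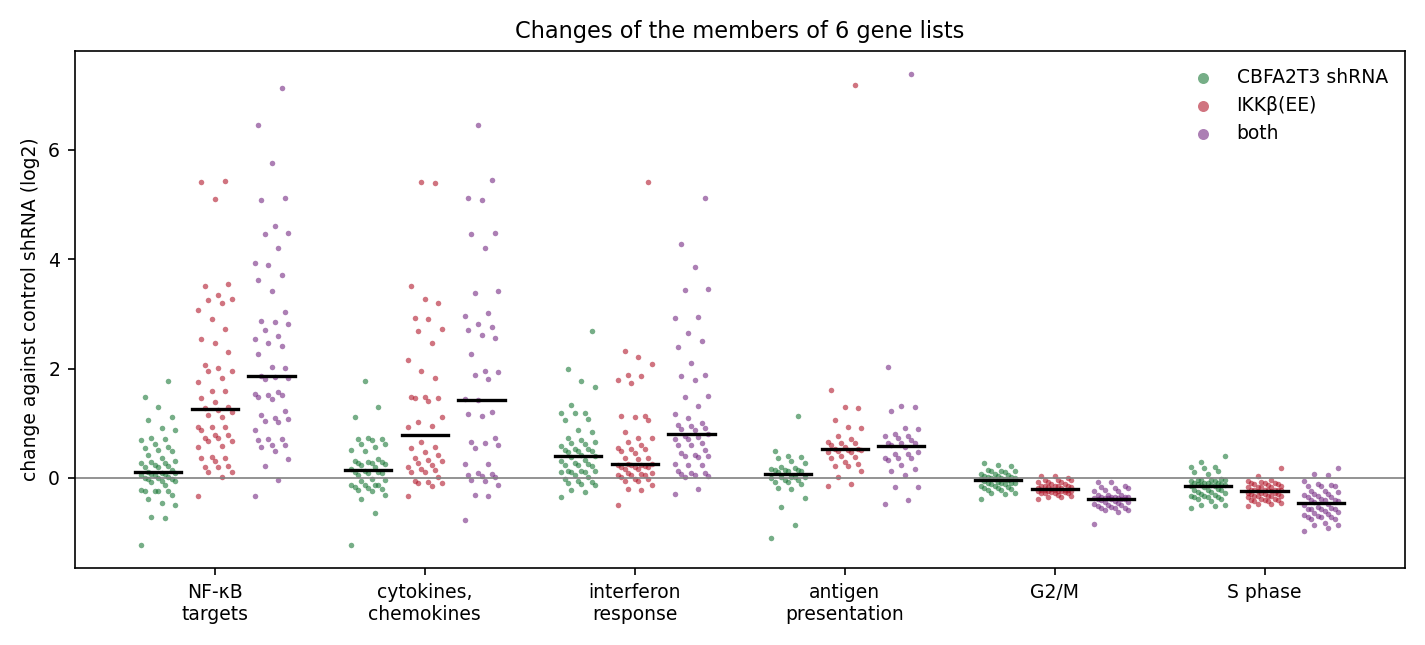
Change against control shRNA (log2, vertical axis) of every tested member of 6 gene lists (horizontal axis) with the CBFA2T3 shRNA (green), IKKβ(EE) (red) or both (purple); each point is 1 gene, spread sideways, and black bars are medians. The NF-κB medians were 0.10, 1.26 and 1.86, and the S-phase medians -0.14, -0.24 and -0.45.

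Both transfections together changed 2064 probe sets against control, 1146 higher and 918 lower. With the replicate block 5810 were called (2878 higher, 2932 lower), the 2064 included. The count was 183 without control 1, 82 without control 2, 1103 without either CBFA2T3 shRNA array, 3645 without replicate 1 of both transfections and 374 without its replicate 2.

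Adding IKKβ(EE) to cells with the CBFA2T3 shRNA raised MS4A1 by 7.30 ± 0.46 (adjusted p = 0.000883), HLA-DQA1 by 6.24 ± 0.51, BCL2A1 by 6.22 ± 0.42, LAMP3 by 5.83 ± 0.55 and EBI3 by 5.82 ± 0.54. AGR2, which the shRNA alone had raised, fell by 2.43 ± 0.35 (adjusted p = 0.0287), followed by LOC441179 (-2.06 ± 0.24), DOP1B (-0.93 ± 0.13), EML6 (-0.91 ± 0.14) and the prostaglandin dehydrogenase HPGD (-0.76 ± 0.12). Of the 54 NF-κB targets 26 rose (48 when adjusted over the list alone, median 1.69, adjusted p = 1.06e-47, and adjusted p = 0.160 with an estimated correlation). Cytokines and their receptors had 14 of 44 called higher, with CCR7 at 5.40 ± 0.24 (adjusted p of the list 5.38e-23, and adjusted p = 0.133 with an estimated correlation), and genes associated with Hodgkin lymphoma 13 of 36, with TRAF1 at 3.79 ± 0.38 (1.72e-20, and adjusted p = 0.185 with an estimated correlation). Antigen presentation genes (4 of 32) and interferon response genes (6 of 51) rose with adjusted p of 1.04e-18 and 1.51e-16 (adjusted p = 0.0794 and 0.185 with an estimated correlation). Immediate early genes (2 of 33 called, DUSP5 at 3.73 ± 0.43 and IER3 at 1.85 ± 0.27), p53 targets (2 of 30, FAS at 3.01 ± 0.40) and apoptosis regulators (3 of 33) rose with adjusted p of 5.68e-09, 2.53e-06 and 0.00332, each with an adjusted p = 0.472 with an estimated correlation. NF-κB pathway components passed with 0 of 32 called (adjusted p = 0.000223, and adjusted p = 0.133 with an estimated correlation). Cholesterol synthesis genes, which the shRNA alone had raised as a group, fell as a group here (4 of 24 higher, median -0.18, 0 called, adjusted p = 0.00338, and adjusted p = 0.503 with an estimated correlation). For this list and for AGR2, both comparisons use the same shRNA arrays with opposite sign. A deviation of those arrays would by itself give a rise and then a fall. G2/M genes (3 of 42 higher) and S-phase genes (2 of 48 higher) also fell as groups with 0 called (adjusted p = 1.73e-09 and 2.74e-05, and adjusted p = 0.518 and 0.725 with an estimated correlation). Called higher in the fit with the replicate block were 45 NF-κB targets, 22 cytokine, 16 antigen presentation, 19 interferon, 6 p53, 5 apoptosis, 6 NF-κB pathway and 12 immediate early genes. It called 1 immediate early and 2 cholesterol synthesis genes lower.

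The comparison called 211 probe sets, 201 higher and 10 lower, and 1244 with the replicate block (891 higher, 353 lower); 3711 had an unadjusted p under 0.05. It called 69 without either control array, 38 and 66 without shRNA replicates 1 and 2, 836 without replicate 1 of both transfections and 108 without its replicate 2. The S-phase list turned to the opposite direction without that replicate 2 (adjusted p = 0.917), and the cholesterol call was lost without that replicate 1 (0.484).

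The last pairwise comparison asked what the CBFA2T3 shRNA changed in cells with IKKβ(EE). HSPA6, a strictly stress-inducible chaperone gene, rose by 3.35 ± 0.17 (adjusted p = 0.00255), SLAMF7, a surface receptor of activated lymphocytes, by 2.80 ± 0.16 (adjusted p = 0.00255) and TOX by 2.91 ± 0.35. The chemokines CCL20 (2.86 ± 0.29) and CCL22 (2.51 ± 0.25, both adjusted p = 0.0253) rose, whereas the monocyte chemokine CCL2 fell by 2.11 ± 0.24 (adjusted p = 0.0298), from 6.0 with IKKβ(EE) alone to 3.89 with both. SDC2 (-2.47 ± 0.26), COX7A2L (-1.75 ± 0.20), the BMP receptor BMPR2 (-1.40 ± 0.14) and SHROOM3 (-1.21 ± 0.12) also fell. CCL20, CCL22 and CCL2 were the only called members of the NF-κB and cytokine lists, which rose as groups (48 of 54 and 33 of 44 higher, medians 0.60 and 0.31, adjusted p = 3.90e-10 and 0.000261). Interferon response genes rose again (49 of 51 higher, 0 called, 21 when adjusted over the list alone, median 0.35, adjusted p = 1.39e-13), and so did genes associated with Hodgkin lymphoma (32 of 36 higher, adjusted p = 4.16e-08), heat shock genes (17 of 19 higher, HSPA6 called, 0.00279) and cholesterol synthesis genes (21 of 24 higher, 0.00331). All 6 of these lists had an adjusted p = 0.546 with an estimated correlation. Immediate early genes (0.00141), apoptosis regulators (0.00228) and MYC and ribosome biogenesis genes (0.000621) passed upward with 0 called, and G2/M (5.64e-06), S-phase (0.000494) and B-cell genes (0.0466) downward with 0 called. The B-cell list had a median of -0.16 and a mean of 0.01. With an estimated correlation their adjusted p = 0.682, 0.546, 0.682, 0.682, 0.682 and 0.610. In the fit with the replicate block 16 NF-κB targets were called higher and 1 lower, 12 cytokine genes higher and 2 lower, 11 Hodgkin genes higher and 1 lower, and 3 B-cell genes higher and 2 lower. Called higher were also 15 interferon, 2 heat shock, 1 cholesterol synthesis, 5 immediate early, 3 apoptosis and 3 MYC list genes.

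There were 35 calls, 21 higher and 14 lower, and 3621 probe sets had an unadjusted p under 0.05. With the replicate block 1117 were called (533 higher, 584 lower), and the B-cell list no longer passed (adjusted p = 0.0677). Leaving out control 1 or control 2 gave 9 calls, either CBFA2T3 shRNA array 16, either IKKβ(EE) array 3, replicate 1 of both transfections 399 and its replicate 2 13. Without that replicate 2 the immediate early (adjusted p = 0.554), apoptosis (0.157), G2/M (0.584), cholesterol (0.285) and B-cell (0.379) calls were lost and the S-phase direction turned (0.231). Without its replicate 1 the MYC (0.241), heat shock (0.0544) and B-cell (0.0618) calls were lost. Without IKKβ(EE) replicate 1 the immediate early (0.307) and S-phase (0.353) calls were lost. Without its replicate 2 it was the MYC (0.611), heat shock (0.149) and B-cell (0.247) calls, and without shRNA replicate 1 or 2 the B-cell call (0.0591 and 0.0528).

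Whether the 2 transfections acted independently was asked with the interaction. It was passed by 3 probe sets, the same 3 with the replicate block, while 531 had an unadjusted p under 0.05. HSPA6 stood at 4.37 with the control shRNA, 4.05 with the CBFA2T3 shRNA, 4.99 with IKKβ(EE) and 8.34 ± 0.11 (SD, n = 2) with both, which exceeded the sum of the single effects by 3.68 ± 0.25 (adjusted p = 0.0180). A further HSPA6 probe set gave 2.05 ± 0.23 and did not pass (adjusted p = 0.125). SLAMF7 stood at 3.29, 3.33, 4.08 and 6.88 ± 0.20 (SD, n = 2), an excess of 2.76 ± 0.23 (adjusted p = 0.0448), and the third probe set, which carries several gene symbols, all of heat shock genes, and is left unnamed, gave 3.67 ± 0.33 (adjusted p = 0.0448). A further 2 probe sets with several heat shock symbols gave 1.40 ± 0.29 and 1.47 ± 0.31 and did not pass. Outside the group with both transfections all 3 lay below the floor on every array, except HSPA6 at 5.17 on IKKβ(EE) replicate 1. CCL22 (2.56 ± 0.35, adjusted p = 0.334), CCL2 (-1.89 ± 0.33, adjusted p = 0.594) and DUSP5 (3.25 ± 0.61, adjusted p = 0.742) did not pass. For CSF1R the excess was 0.01 (95% confidence interval -0.57 to 0.58), and for CBFA2T3 itself 0.13 ± 0.23. Of the 24 lists 8 passed, and their values stand with the results marked for a closer look.

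The interaction count was 24 without replicate 1 of both transfections, 1 without IKKβ(EE) replicate 1 and 0 without any 1 of the other 6 arrays. Without 1 array the HSPA6 excess stayed between 3.49 and 3.86. Its adjusted p was 0.0750 and 0.139 without controls 1 and 2, 0.236 and 0.107 without shRNA replicates 1 and 2, 0.0785 without IKKβ(EE) replicate 2 and 0.0657 without replicate 2 of both. SLAMF7 passed only without replicate 1 of both (adjusted p = 0.0170), with the others from 0.0657 to 0.457, and it also missed the threshold with trend and robust moderation (0.0593).

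**Figure D3:**
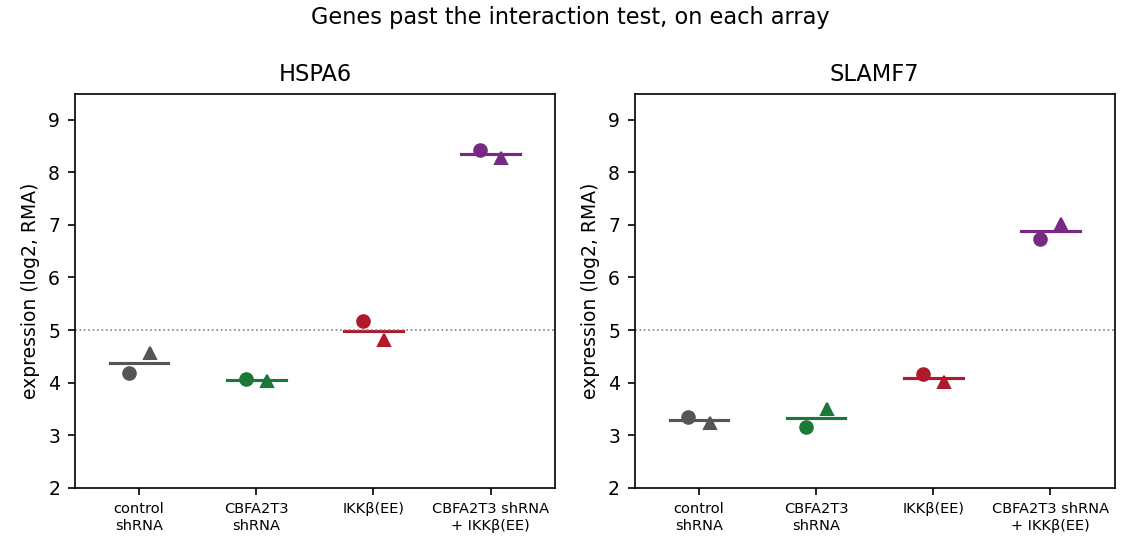
Expression (log2, RMA) of HSPA6 and SLAMF7 on each array, by group; circles are replicate 1, triangles replicate 2, bars the mean of the 2 arrays, and the dotted line is the floor at log2 5. With both transfections the means were 8.34 and 6.88, against 4.99 and 4.08 with IKKβ(EE) alone.

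Each single effect was also compared on arrays that the first comparison had not used. Of the 169 probe sets called with the CBFA2T3 shRNA against control, 167 (98.8%) had the same sign when the shRNA was added to IKKβ(EE). Among all tested probe sets the share was 74.2%. The median size ratio of the 169 was 0.70, but only 17 were called in both with the same sign. Because the 169 were selected in the first comparison, this ratio can shrink without a difference between backgrounds. Of the 35 called on the IKKβ(EE) background 30 (85.7%) had the same sign without it, and the changes of all tested probe sets correlated across the 2 backgrounds with Pearson's r of 0.71 and Spearman's rho of 0.68. For IKKβ(EE), 56 of 56 had the same sign in cells with the shRNA, against 74.5% of all tested probe sets. Their median size ratio was 0.96, and 47 were called in both. The other way round 208 of 211 (98.6%) had the same sign, and the correlation was r of 0.80 and rho of 0.66. These correlations are across probe sets, which are not independent replicates. The calls of the 2 single transfections shared 3 genes upward, ANXA1, SLC2A13 and PYHIN1, and 2 downward, MN1 and RASSF10. SDC2, on a further probe set, fell with the shRNA and rose with IKKβ(EE). SLC2A13 and PYHIN1 were chosen after their values were seen. Over all tested probe sets the 2 single effects correlated at 0.30, where unchanged groups against the same 2 controls gave 0.50 on average. The covariance was 0.0377 against 0.0177 in the simulations. Unrelated changes also lower a correlation, so the value under 0.50 does not tell how the 2 effects relate. The simulations ignored the pairing of replicates, so their covariance is probably too large. The 2 shared controls were not split between the comparisons, which would have left a single control array for each. The correlation was 0.44 without control 2 and 0.19 without shRNA replicate 2.

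**Figure D4:**
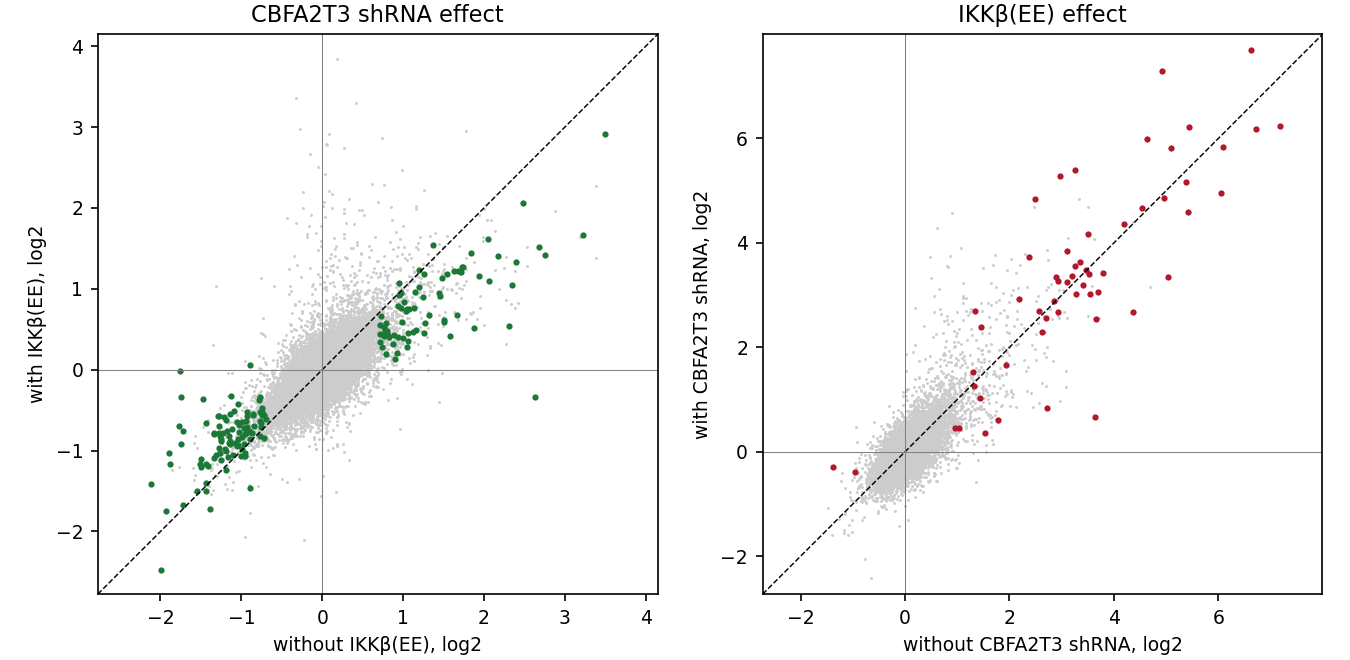
Left, log2 change with the CBFA2T3 shRNA without IKKβ(EE) (horizontal) and with it (vertical); right, log2 change with IKKβ(EE) without the shRNA (horizontal) and with it (vertical). Each point is 1 of 24481 probe sets, coloured points are the 169 and 56 called on the horizontal axis, and the dashed line marks equal change; 167 and 56 of them had the same sign on both axes.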

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

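Tests of the heat shock response, of the shRNA construct, within and between replicates of the NF-κB targets, and without 1 array with the replicate block were chosen after the results were seen. The interaction itself was planned. The other tests of a cause were set before their own values were seen, but after the results had marked the patterns they concern. Those of dose also drew on the IKBKB levels. In this part, beforehand is meant in this narrower sense. The interaction, which tests whether the CBFA2T3 shRNA effect differs with and without IKKβ(EE), marked 3 probe sets: HSPA6 (3.68), SLAMF7 (2.76) and a probe set with several gene symbols (3.67). It also marked 8 gene lists, of which none passed with an estimated correlation (adjusted p from 0.794 to 0.878). Above the sum of the single effects lay NF-κB targets (median 0.31, adjusted p = 1.40e-11), genes associated with Hodgkin lymphoma (0.18, adjusted p = 0.000130), MYC and ribosome biogenesis genes (0.18, adjusted p = 0.000356), heat shock genes (0.20, adjusted p = 1.29e-05) and cytokines with their receptors (0.11, adjusted p = 0.000356). Below it lay B-cell genes (-0.15, adjusted p = 0.00317), G2/M genes (-0.15, adjusted p = 6.98e-05) and histone genes (-0.31, adjusted p = 0.0490, or 0.0598 with the replicate block). Except for heat shock genes, each of these calls was lost without replicate 2 of both transfections or, for the MYC list, without its replicate 1 (adjusted p = 0.431). The values without that replicate 2 were 0.104 (NF-κB), 0.806 (Hodgkin), 0.237 (cytokines), 0.169 (B-cell), 0.581 (G2/M, with the direction turned) and 0.496 (histone). Other arrays ended some of them too: control 1 the B-cell (0.124), G2/M (0.108), MYC (0.934) and histone (0.189) calls, control 2 the histone call (0.0542), shRNA replicate 1 the Hodgkin (0.0520) and cytokine (0.0844) calls, shRNA replicate 2 the MYC (0.104) and histone (0.285) calls, IKKβ(EE) replicate 1 the Hodgkin (0.116), G2/M (0.0931) and histone (0.155) calls, and IKKβ(EE) replicate 2 the B-cell (0.0833) and MYC (0.935, direction turned) calls. Those fits had no replicate block, so a left-out array also shifted its group by what the replicates differed. With the block the NF-κB, MYC and heat shock calls passed without any 1 of the 8 arrays. The B-cell call was lost without control 1 (0.127), shRNA replicate 1 (0.0541), IKKβ(EE) replicate 2 (0.0694) and replicate 2 of both (0.238), and the G2/M call without control 1 (0.973, direction turned), shRNA replicate 2 (0.0791) and replicate 2 of both (0.529, direction turned). The Hodgkin and cytokine calls were lost without control 1 (both 0.318) and without replicate 2 of both (0.491 and 0.138).

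HSPA6 was called only where both constructs were present. A general heat shock response stays open: the other 18 genes of the list had a median change with both against control of 0.01 (bootstrap upper limit 0.14), DNAJB1 (-0.29 ± 0.18) and HSPH1 (0.08 ± 0.20) among them, but this left out 3 probe sets with several heat shock symbols, called at 2.24 to 4.74, and DNAJB4 rose by 1.17 ± 0.20. A single deviating array is argued against, since the excess stayed at 3.60 or more without either array of both transfections, with and without the replicate block, although its adjusted p without the block was 0.0657 without replicate 2. On the probe set that rose, the IKBKB difference to IKKβ(EE) alone was 1.58 in the replicate 2 arrays and 0.60 in the replicate 1 arrays. The HSPA6 differences were 3.46 and 3.25, apart by 0.21. The margin set beforehand (1 SE of the fit, 0.175) would have counted this in favour of dose. By the fit without the replicate block that margin was too narrow, because a difference between pairs of single arrays then has an SE of 0.350. This wider margin was set after the value was seen, and it leaves the pairing of replicates out of account. With the wider margin, IKBKB dose and an effect of CBFA2T3 loss cannot be told apart for this gene.

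The excess of NF-κB targets with both transfections may come in part from 1 array, or from the IKKβ dose. The list failed without replicate 2 of both, but with the replicate block it passed without any 1 array. Its median excess was 0.31 with all arrays. Without the block it was -0.02 without replicate 2 of both and 0.82 without replicate 1 of both. With the block these values were 0.09 and 0.76, and the excess was 0.19 without control 1 and 0.60 without control 2. Within replicates 1 and 2, which share no array, the median excess was 0.30 and 0.43, with 37 and 45 of the 54 genes above 0. An excess in both argues against 1 array as its only source. Its size still hung on replicate 2 of both, so a share from 1 array stays open. For dose, 50 of the 54 targets (92.6%, against 47.3% of all genes) differed more from IKKβ(EE) alone in the replicate 2 arrays. There the IKBKB difference was larger on the probe set that rose. Against dose, that probe set was lower on IKKβ(EE) replicate 2 than 1 (-0.46), while 38 of the 54 had a larger replicate difference there than in control. The other 2 IKBKB probe sets were higher on IKKβ(EE) replicate 2 than on replicate 1 (9.18 against 8.77, and 7.37 against 6.88). The list passed after cyclic loess (adjusted p = 2.50e-11), so the call did not rest on intensity-dependent differences left after RMA. Scaling cannot be decided further, because RMA had already set the arrays to a common distribution. An effect of CBFA2T3 loss on the NF-κB response is the biological alternative that the design names. It stays open alongside dose and a share from 1 array. By the rules set beforehand, dose and 1 array would each have counted as a cause. The median difference to IKKβ(EE) alone was 0.79 in the replicate 2 arrays and 0.38 in the replicate 1 arrays. Dose and a share from 1 array were left undecided only after the results were seen. This came from the comparison with control replicates, the values within replicates and the fits with the block.

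Interferon response genes rose with the CBFA2T3 shRNA in camera, although not with an estimated correlation (adjusted p = 0.835) or with fry (adjusted p = 0.147). A single array is argued against by an adjusted p of at most 1.18e-06 without any 1 of the 8 arrays. With the replicate block the largest adjusted p was 0.000123, and the median of 0.40 was 0.18 without shRNA replicate 2. The list also passed after cyclic loess (adjusted p = 2.07e-08), so the call did not rest on intensity-dependent differences left after RMA. Scaling stays undecided beyond that here too, because the loess started from arrays that RMA had set to a common distribution. Under a stricter rule, tried after the results were seen and not kept, by which the median was not to fall by 2 times or more, a single array would have stayed open. The rise was also present on the IKKβ(EE) background, in arrays not used for the first comparison, with a median of 0.35. A reaction to the shRNA construct and an effect of lower CBFA2T3 cannot be told apart, because the arrays hold 1 shRNA against CBFA2T3, with no rescue, and the control arrays are titled mock although their labels say control shRNA.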

How the results depend on the processing

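The replicate block with an estimated correlation, with fry or without 1 array was added after the data were seen, and all other alternatives were planned. The counts of changed probe sets were 169 with the shRNA, 56 with IKKβ(EE), 2064 with both, 211 for both against the shRNA, 35 for both against IKKβ(EE) and 3 for the interaction. Without a floor IKKβ(EE) gave 89, both against IKKβ(EE) 58 and the interaction 6. Trend and robust moderation gave 96 for IKKβ(EE) and 1 for the interaction, and array weights gave 449 for the shRNA. With 1 probe set per gene, where fewer were tested, both gave 1120 and both against the shRNA 117. The replicate block gave 1890, 831, 5810, 1244 and 1117 in the order above and changed no interaction call. The arrays of the compared groups alone, with 2 residual degrees of freedom, gave 359, 124, 532, 37 and 6. Leaving out 1 array gave 0 to 297, 5 to 214, 82 to 3645, 38 to 836, 3 to 399 and 0 to 24.

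CBFA2T3 with its shRNA (change -0.999) passed the threshold with a floor at log2 6 (adjusted p = 0.04996), trend (0.0389), weights (0.0294), loess (0.0479, change -0.997), 1 probe set per gene (0.0405), the block (0.01002) and the compared groups alone (0.0380). Against IKKβ(EE) it passed with the block (0.0255, change -0.87). Without 1 array these changes ranged from -1.14 to -0.85 and from -1.07 to -0.67, and with both against control from -1.42 to -1.03.

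Lists past camera numbered 4, 13, 11, 12, 12 and 8. With an estimated correlation, with or without the block, 0 passed in all 6 comparisons. Fry gave 0, 2, 9, 6, 0 and 0, and with the block 0, 4, 12, 7, 0 and 0, and camera with the block gave 7 for the shRNA. Without 1 array they numbered 2 to 8, 11 to 14, 11 to 13, 11 to 14, 6 to 12 and 5 to 12, and with the block 2 to 12, 12 to 16, 11 to 12, 11 to 13, 8 to 14 and 4 to 12. Lists turned direction in 9 fits, each without 1 array, 3 of them with the block. Without the block and without IKKβ(EE) replicate 2 these were MYC genes for IKKβ(EE) (adjusted p = 0.918, range without 1 array 5.45e-08 to 0.954) and the interaction (0.935, range 1.91e-10 to 0.935). Without replicate 2 of both they were S-phase genes against the shRNA (0.917, range 2.03e-14 to 0.917), against IKKβ(EE) (0.231, range 1.03e-14 to 0.353) and for the interaction (3.56e-07, range 9.57e-13 to 0.740), and G2/M genes for the interaction (0.581, range 3.94e-15 to 0.581). With the block the G2/M interaction turned without control 1 (0.973) and replicate 2 of both (0.529), and the S-phase interaction without the latter (3.58e-05).

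Without 1 array, the shRNA effect kept its direction between backgrounds for 95% to 100% of called probe sets, where any were called. Without control 1, control 2 or shRNA replicate 2 nothing was called and the share is undefined. The 95%, without IKKβ(EE) replicate 2, rested on few calls. For IKKβ(EE) the share was 98.6% to 100%, and the correlation of the 2 single effects ranged from 0.19 to 0.44. Of the values of named genes under all alternatives, 983 stayed on their side of the threshold and 264 lost it, 244 of these without 1 array. Except where fewer arrays or probe sets entered, the cause was not tested. Signal close to background limits genes under log2 5.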

Other observations

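The tests in this part were all chosen after the results were seen. Replicates 2 and 1 were compared over the 4 groups. With the replicate number as a term, 2180 probe sets differed, 1273 higher and 907 lower in replicate 2. CD9, a tetraspanin, was higher there by 1.71 ± 0.10 (log2, adjusted p = 0.00847), the glucose-responsive TXNIP by 1.31 ± 0.09, the stress genes DDIT3 and TRIB3 by 0.98 ± 0.08 and 1.22 ± 0.11, the quiescence-associated KLF2 by 1.22 ± 0.11 and the activation marker CD69 by 1.06 ± 0.10, each in 4 of 4 groups. CCNE1, a cyclin of the G1 to S transition, changed by -0.61 ± 0.07, and the chaperone genes FKBP4 and HSPE1 by -0.54 ± 0.07 and -0.51 ± 0.07. These genes were chosen after their values were seen.

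As lists, MYC and ribosome biogenesis genes (16 of 39 called lower, median -0.30, adjusted p = 2.44e-13) and S-phase genes (9 of 48 called lower, median -0.28, adjusted p = 2.74e-11) were lower in replicate 2. Immediate early genes (15 of 33 called higher, median 0.50, adjusted p = 1.10e-09), NF-κB targets (12 of 54, median 0.40, adjusted p = 2.87e-09) and glycolysis and hypoxia genes (13 of 35, with 1 lower, median 0.28, adjusted p = 1.48e-05) were higher. So were genes associated with Hodgkin lymphoma (10 of 36, median 0.33, adjusted p = 7.33e-06), p53 targets (4 of 30, median 0.19, adjusted p = 0.000893), stress response genes (12 of 44, with 1 lower, median 0.14, adjusted p = 0.00162) and cytokines with their receptors (8 of 44, median 0.14, adjusted p = 0.00256). Cholesterol synthesis genes (1 of 24, median 0.13, adjusted p = 0.0367) and apoptosis regulators (5 of 33, median 0.14, adjusted p = 0.0448) passed upward too. Heat shock genes (4 of 19 called lower, median -0.16, adjusted p = 0.00256) and G2/M genes (0 of 42 called, median -0.09, adjusted p = 0.0202) passed downward. These 13 lists had an adjusted p = 0.546 with an estimated correlation, except cholesterol synthesis (0.590) and G2/M genes (0.758). The NF-κB difference was not equal in the groups. Its median was 0.06 with the control shRNA, 0.20 with the CBFA2T3 shRNA, 0.36 with IKKβ(EE) and 0.84 with both. The mean of the poly-A spike-in probe sets on replicates 1 and 2 was 6.58 and 6.35 with the control shRNA and 6.51 and 6.28 with the CBFA2T3 shRNA. It was 6.20 and 6.22 with IKKβ(EE) and 6.14 and 5.85 with both. All arrays with IKKβ(EE) thus lay below those without it, and replicate 2 of both was lowest. Whether this affected the comparisons was not tested. The difference between the 3′ and 5′ ACTB control probe sets ran from 1.25 to 1.94.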
